A study of Lactuca sativa with 3 samples.

How the data were processed

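Small RNAs were sequenced from 3 lettuce (Lactuca sativa) RNA samples, cultivar Salinas per the series' design text: leaves, flowers, and leaves harvested 7 days after inoculation with Bremia lactucae, strain CA-III. The labels call Bremia lactucae a fungus. It is an oomycete that causes lettuce downy mildew. Each group had 1 library, so no spread between replicates was measured and no p-value is given.

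Per the labels' protocols, total RNA was extracted with TriReagent, RNA of about 18 to 33 nt was cut from a gel, and the libraries were sequenced by Illumina's sequencing by synthesis. Per the series' design text, the authors removed adapter sequences and counted each distinct sequence with PERL scripts. An aligner, a genome build and a minimum abundance are not given in the sources used here. Per the file headers, each file lists distinct trimmed sequences with their raw read count, which is the count used throughout. The deposited score beside it is the authors' tags per 1000000 reads, rounded to whole numbers with a minimum of 1. It summed to between 1170779 and 1573808 per library because every sequence read once is listed as 1. The score was used only to check the library total: recomputed from the counts, 100% of the listed values in each library lay within 1 of the deposited ones.

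The libraries held 1778372 reads (leaf), 2109764 reads (flower) and 1503257 reads (infected leaf). Reads per 1000000 (RPM) are raw counts divided by these totals. Shares carry exact Clopper-Pearson 95% intervals, RPM exact Poisson 95% intervals, and ratios between libraries exact conditional binomial 95% intervals. A count of 0 was taken as 3 reads in a ratio, which is 1.69, 1.42 and 2.00 RPM in the leaf, flower and infected leaf libraries. Reads amplified by PCR without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. A ratio compares 2 libraries and not the conditions in general.

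Conserved families were found by matching reads to 63 reference sequences of 42 families, written from general knowledge of plant and animal microRNAs and not checked against a database. A read was assigned to the nearest family when it had the same 5' end, a length within 1 nt of the reference and at most 2 mismatches. The families were grouped in lists before the data were examined: development, nutrient, copper, silencing, defence, other, and control lists of crucifer and animal families. A family was called higher or lower when its RPM differed at least 2-fold with an interval that excluded 1, among families with at least 30 reads over both libraries. List medians were set beside 10000 random lists of the same size. These were drawn from single sequences of 20 to 22 nt outside the families, among the 50 nearest in abundance to each family. The largest families had more reads than nearly all single sequences, so for them the match in abundance was loose. As a background of the matching rule, 10 shuffled copies of every plant reference were searched. Reads of 18 nt or more that matched exactly within the 5.8S ribosomal RNA of only 1 of plant, oomycete, fungus and human were counted per organism. These 5.8S sequences, and those of the other arthropod, vertebrate and crucifer small RNAs, were also written from general knowledge and not checked against a database. The opposite strand of a microRNA duplex (the partner strand) was searched among sequences with at least 100 reads by pairing with 2-nt 3' overhangs and a penalty of at most 3.5, with 0.5 for a G:U pair, and reads near a partner by the family matching rule were counted with it.

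The sequences named in the main comparisons followed a rule set before the data were examined. It took every called family up to 12 per direction and the 3 most abundant sequences of each library. Among sequences with at least 200 reads, it took the 5 with the highest and the 5 with the lowest ratio. Sequences named under the other observations did not follow this rule. Bases are not printed for sequences that could belong to another organism.

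Matching and calling were tested on simulated data. References with 0, 1 or 2 substitutions were assigned to their family in 100.0% of cases, those with 3 in 1.0%, and 0 of 100000 random sequences were assigned. The rule allows 2 mismatches, so the share up to 2 shows only that families were not confused. Random sequences rarely lie that near a reference, so their count says little of related sequences. With counts drawn for 5734 sequences of the flower and leaf comparison, 88.0% of 2.83-fold changes, 99.0% of 8-fold changes and 1.19% of unchanged sequences were called. For 5979 sequences of the infected leaf and leaf comparison, these shares were 85.0%, 100% and 1.00%. The simulated counts were Poisson draws around a mean shared by both libraries. They held no variation by PCR, library or plant, so these shares cover counting error only.

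Alternatives covered the reads counted, the mismatches and 5' end allowed, the minimum of reads, and the scaling, including TMM (edgeR 4.0.16) and median-of-ratios size factors (DESeq2 1.42.0) computed over the families. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used. No genome was used here, so sequences have no coordinates, and genome-matching shares and phased loci were not analysed here.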

Results

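Small RNA reads of 18 to 33 nt were counted in 1 leaf library, 1 flower library and 1 library of leaves infected with the downy mildew pathogen Bremia lactucae. The leaf library held 1778372 reads of 701595 distinct sequences, the flower library 2109764 reads of 1204414, and the infected leaf library 1503257 reads of 615603. Thinned to 1503257 reads, the flower library was expected to hold 882933 distinct sequences against 603951 in leaf. Only 39954 of the 2338282 distinct sequences occurred in all 3 libraries, and these held 54.5% of leaf reads, 36.9% of flower reads and 53.6% of infected leaf reads. With 1 library per group, none of the differences has a replicate check.

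The question of the tissue comparison was how small RNA populations differ between flowers and leaves. Flowers carried far more 24-nt small RNAs, the class that directs DNA methylation at transposons and repeats in plants. The 24-nt share of reads was 22.95% in flower (95% interval 22.89 to 23.01) and 7.38% in leaf (7.34 to 7.42), a 3.11-fold difference (3.09 to 3.13). Its size depends on the reads counted: it was 7.35-fold without sequences read once and 2.02-fold when each distinct sequence counted once. The 23-nt share was 1.70-fold higher in flower. The 21-nt class, which holds most microRNAs, made up 51.5% of leaf reads and 37.0% of flower reads, so the ratio of 21-nt to 24-nt reads was 6.99 in leaf and 1.61 in flower. The 24-nt reads began with A in 83.0% of leaf and 83.8% of flower reads, and the 21-nt reads with T in 55.3% and 60.2%. The infected leaf library had 6.99% of 24-nt reads (6.95 to 7.03) and 50.6% of 21-nt reads (50.5 to 50.6), close to leaf. Its 24-nt share was 0.947 times that of leaf, an order that turned when sequences read once were left out (1.64% against 1.19%).

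**Figure D1:**
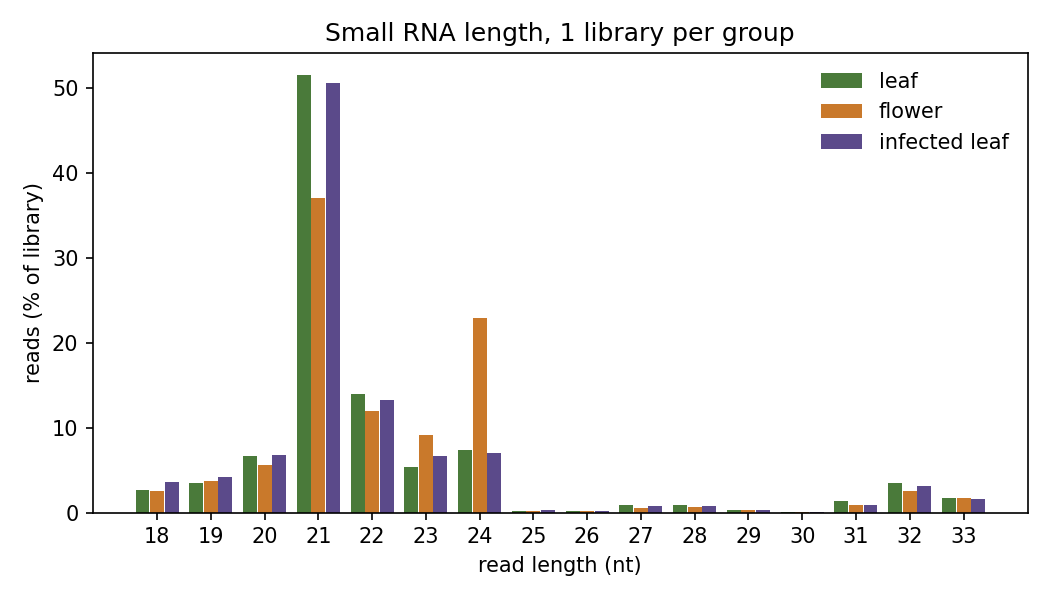
Share of reads (percent of the library) at each read length from 18 to 33 nt, with 1 bar per library (leaf, flower, infected leaf). The 21-nt class is highest in each library, at 51.5%, 37.0% and 50.6%, and the 24-nt bar stands at 22.95% in flower against 7.38% in leaf and 6.99% in infected leaf.

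Reads of conserved microRNA families made up 6.74% of leaf (6.70 to 6.78), 7.02% of flower (6.99 to 7.06) and 8.93% of infected leaf reads (8.89 to 8.98). With no mismatch allowed, the flower share of 2.78% lay below the leaf share of 4.22%. The family miR165/miR166, which restrains HD-ZIP III transcription factors in organ polarity, held 24.3%, 59.2% and 33.27% of these reads, the most of any family in each library when 2 mismatches were allowed. With none allowed miR172 led in leaf and miR167 in the other libraries, and with up to 1 miR172 led in leaf and miR156 in infected leaf. The families miR408, miR529, miR827, miR828, miR845 and miR858 had no read with the same 5' end as their reference. When the 5' end was allowed to shift by up to 2 nt, miR408 had 63, 77 and 74 reads and miR858 30, 33 and 1.

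In flower against leaf, 5 of 24 families were at least 2-fold higher and 9 were lower. The family miR319, which targets TCP genes of leaf and petal growth, was 12.1-fold higher (4.97 to 38.5), on 72 reads in flower and 5 in leaf. The family miR165/miR166 rose from 16376 to 41618 reads per 1000000 (RPM), 2.54-fold (2.51 to 2.57). The tasiR-ARF small RNAs, which repress auxin response factors, rose 2.43-fold (2.17 to 2.74), miR398 2.21-fold (1.42 to 3.52) and miR169 2.15-fold (1.76 to 2.65).

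The silencing list fell in 4 of its 5 measured members and rose in tasiR-ARF alone. Of these, miR168, the regulator of ARGONAUTE1, fell from 10160 to 1769 RPM, 5.74-fold (5.54 to 5.95). The AGO2 regulator miR403 fell 3.37-fold (2.70 to 4.22), miR390, the trigger of tasiR-ARF production, 2.37-fold (2.09 to 2.69), and the DICER-LIKE1 regulator miR162 2.11-fold (1.87 to 2.38). The calls of miR390 and miR162 ended under scaling by the median of ratios (1.64-fold and 1.46-fold) and by TMM (1.58-fold and 1.40-fold). Outside this list, miR159, which targets GAMYB-like genes, fell 6.21-fold (5.34 to 7.25), miR530 6.29-fold (3.87 to 10.7), miR395 of sulfate assimilation 3.07-fold (1.85 to 5.28), the NB-LRR regulators miR482/miR472/miR2118 6.17-fold (2.33 to 20.6, on 5 and 26 reads), and miR477 23.7-fold (6.15 to 203, on 2 and 40 reads).

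By list, the development families counted 2 higher, 1 lower and 8 in neither class, among them miR156, whose 1.86-fold fall became a lower call with no mismatch (3.44-fold) and with up to 1 (2.37-fold). The list had a median log2 ratio of 0.19, at percentile 99.4 of random lists, whose median was -0.88. The match in abundance was loose for the largest families, most of which are in this list. All 24 families together also lay high among random lists, with a median of -0.35 against -0.85 (percentile 98.9), and with no mismatch allowed the development median turned to -0.12. The silencing list had a median of -1.24, at percentile 29.1, so its median did not stand apart from random lists although 4 of its members fell. The nutrient list counted 1 higher and 1 lower of 3, with a median of 0.69 (percentile 91.9), and the copper list 1 higher of 2, with a median of 0.81 (percentile 86.0). The defence list had 1 measured member, miR482/miR472/miR2118. Scaling moved every family by 0.53 (median of ratios) or 0.59 (TMM) on the log2 scale, which gave 9 higher and 7 lower in place of 5 and 9. The share of higher calls was then 56.2% in place of 35.7%, and no called family changed direction. The calls of miR398, miR477 and miR482/miR472/miR2118 rest on sequences with mismatches, save 1 leaf read of miR477, and with none allowed tasiR-ARF was at 1.36-fold.

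Among 853 sequences with at least 200 reads over both libraries, 115 were at least 2-fold higher in flower and 351 lower, with a median log2 ratio of -0.76 over all of them. The split depends on the scaling: it was 184 and 244 by the median of ratios, and 194 and 239 by TMM. The sequence TAATGTGATGAAGGCGTTGAG had 847 reads in flower and 1 in leaf, 714-fold (128 to 28233). At 0 leaf reads, taken as 3, CATAGTCATTGTCGGCGGCAT (1625 flower reads) was 457-fold higher (lower bound 371). On the same terms TGCTTCCATAGTCATTGTCGG (1071) was 301-fold higher (lower bound 244) and TTGCTAGCATACTCGTAGACT (954) 268-fold (lower bound 218). The sequence CTTCTGTATCTTGGCTATTCC had 268 flower reads and 1 leaf read. At the other end, GCTTTTTATACGCGATGGTCG had 1960 leaf reads and 1 flower read, 2325-fold lower (417 to 91888), and TGAAAATAGGAACGATGGCTT had 856 and 2. The sequence TTAATGTGATGAAGGCGATGA, with 952 leaf reads and 0 flower reads, taken as 3, was 376-fold lower (lower bound 306). Sequences of 18 nt and 20 nt, of unknown origin, were 476-fold and 402-fold lower. Several of these extremes have a 1-base variant with the opposite pattern: TAATGTGATGAAGGCGATGAG had 864 leaf reads and 0 in flower, and differs from TAATGTGATGAAGGCGTTGAG by A17T, counted from 1 at the 5' end.

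The most abundant leaf sequence was the 22-nt TCGCCTCTAAAACTTAAGAAGA, at 22229 RPM against 7926 in flower and 9707 in infected leaf. It was followed by AGAATCTTGATGATGCTGCAT of miR172 (13697, 7032 and 2680) and TTGGACTCACGTGCAGCAACC (11503, 6042 and 14043), which also led infected leaf. In flower the leaders were TCGGACCAGGCTTCATTCCTT (15476) and TCGGACCAGGCTTCATTCCTC (14804), both of miR165/miR166. In infected leaf the next were TCGGACCAGGCTTCATTCCCC of miR165/miR166 (12245) and TGAAGCTGCCAGCATGATCTG of miR167 (11496).

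The infection comparison asked how small RNAs of leaves at 7 days after inoculation differ from those of leaves without it. Reads that matched only oomycete 5.8S ribosomal RNA numbered 42 in the infected leaf library, 27.9 RPM (20.1 to 37.8). There were 0 in each of the others, with upper limits of 2.07 RPM in leaf and 1.75 RPM in flower. Plant 5.8S fragments, a sign of RNA breakdown or of ribosomal RNA content, were also 1.83-fold more frequent in infected leaf than leaf (1.78 to 1.88), at 8068 against 4405 RPM. They were 1.36-fold less frequent in flower than leaf.

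In infected leaf against leaf, 2 of 22 families were at least 2-fold higher and 10 were lower. The family miR156, which holds back SPL genes and marks the juvenile phase, rose from 9758 to 26091 RPM, 2.67-fold (2.63 to 2.72). The copper-responsive miR398, which targets superoxide dismutase transcripts, rose 4.57-fold (3.01 to 7.13), on 112 and 29 reads, all but 1 of them with a mismatch to the reference. The family miR172, which targets AP2-like genes and marks the adult phase, fell from 16157 to 3072 RPM, 5.26-fold (5.10 to 5.43).

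The development list counted 1 higher, 5 lower and 4 in neither class. Among the 4 was miR165/miR166, at 1.81-fold, which became a higher call with no mismatch (3.52-fold), with up to 1 (2.05-fold) and by the median of ratios (2.98-fold). Besides miR172, its members miR159 fell 4.14-fold (3.58 to 4.81), miR394 3.33-fold (2.73 to 4.08), miR164, a regulator of NAC genes, 3.10-fold (2.77 to 3.48) and miR170/miR171, a regulator of GRAS genes, 2.17-fold (1.87 to 2.53). In the silencing list, miR403 fell 3.97-fold (3.04 to 5.25) and tasiR-ARF 3.25-fold (2.60 to 4.08), while miR168 was at 1.12-fold (1.10 to 1.14), miR162 at 1.72-fold (1.57 to 1.89) and miR390 at 0.841-fold (0.752 to 0.940), of which miR168 and miR390 changed direction under another scaling. In the nutrient list miR169, a regulator of NF-YA genes, fell 28.5-fold (10.9 to 106), on 4 and 135 reads, and miR395 was at 0.664-fold with an interval that includes 1 (0.417 to 1.04). In the copper list miR397 was at 0.576-fold. The defence member miR482/miR472/miR2118 was at 1.78-fold (1.05 to 3.04). By the median of ratios it became a higher call (2.92-fold), as did miR162 (2.83-fold) and miR167 of the development list (2.63-fold). Of the other families, miR530 fell 3.90-fold (2.46 to 6.41). The family miR477, at 0 reads against 40 and with 0 taken as 3, fell 11.3-fold (lower bound 8.75). Both comparisons were made against the same leaf library. The families miR159, miR403, miR530 and miR477 were called lower in flower as well, and miR398 was called higher in both. For these, a level peculiar to that leaf library cannot be told apart from a change with infection.

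The list medians were -0.92 for development (percentile 11.6 of random lists, loosely matched for the largest families), -0.25 for silencing (48.6) and -2.71 for nutrient (8.5). The copper median was 0.70 (80.2) and turned to -0.81 with no mismatch allowed. All 22 families together had a median of -0.76 against -0.23 in random lists (percentile 6.3), a lower percentile than that of any single list. Scaling by the median of ratios moved every family by 0.72 on the log2 scale and gave 6 higher and 7 lower, in place of 2 and 10, with 46.2% higher in place of 16.7%, while scaling to conserved microRNA reads gave 2 higher and 13 lower. The median of ratios ended the calls of miR164 (1.89-fold), miR170/miR171 (1.32-fold) and tasiR-ARF (1.98-fold), and turned the silencing median to 0.47. No called family changed direction under any scaling. Plant 5.8S fragments were 1.83-fold higher in this library beside all of these lists.

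**Figure D2:**
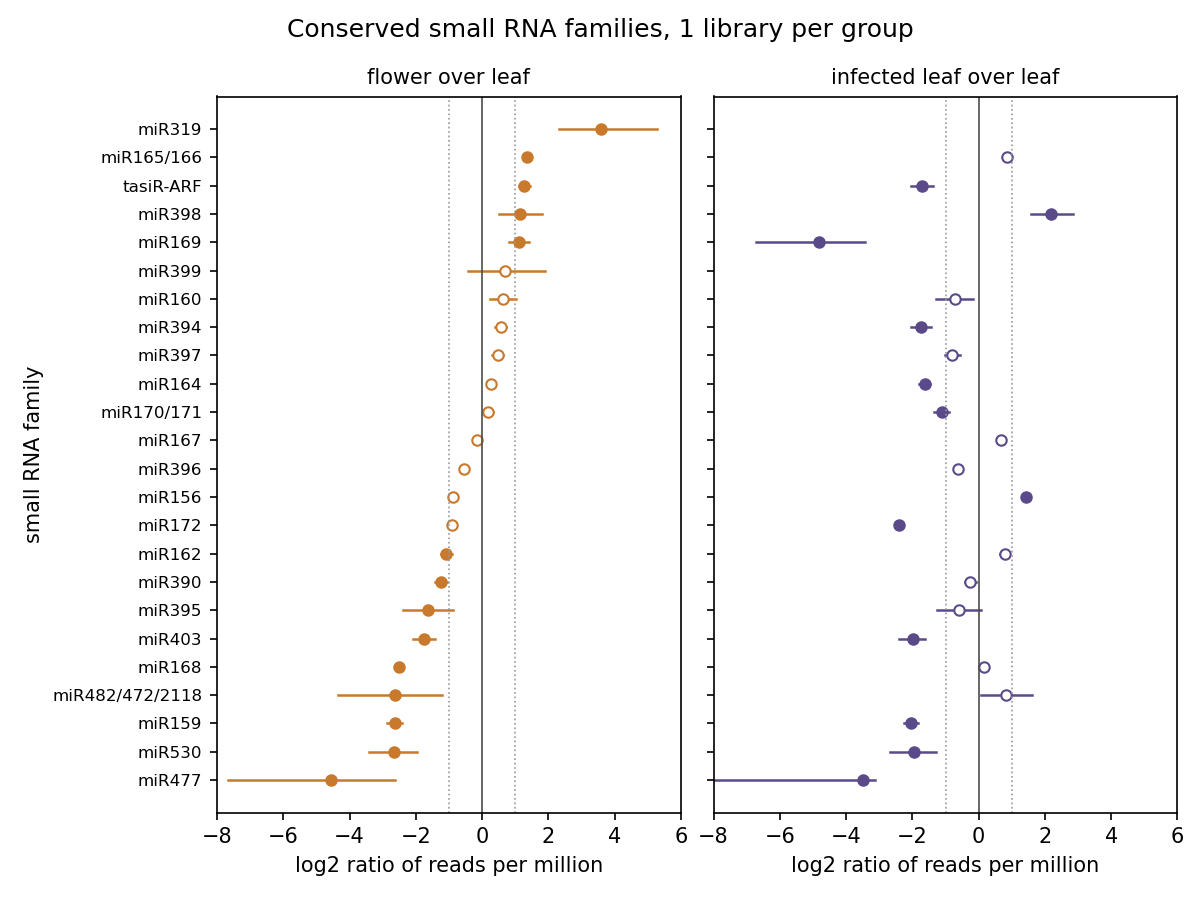
Log2 ratio of RPM of each small RNA family in flower over leaf (left) and infected leaf over leaf (right), with exact 95% counting intervals as lines and filled points for families at least 2-fold apart with an interval that excludes 1. Dotted lines mark log2 ratios of -1 and 1, an interval that reaches 0 reads is drawn to the left edge, and families with fewer than 30 reads are left out. The count of filled points is 5 higher and 9 lower on the left, and 2 higher and 10 lower on the right.

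Among 879 sequences with at least 200 reads over both libraries, 183 were at least 2-fold higher in infected leaf and 219 lower, with a median log2 ratio of -0.07. By the median of ratios the order turned, to 349 higher and 114 lower, and relative to conserved microRNA reads the counts moved the other way, to 122 and 321. Of the 879, 6 were 24 nt long, and all 6 were higher, with a median log2 ratio of 4.16. The sequence TAATGTGATGAAGGCGTTGAG led, at 2034 reads against 1 (2406-fold, 431 to 95088). With 0 reads taken as 3, it was followed by TTGCTAGCATACTCGTAGACT (570 against 0, 225-fold, lower bound 182). Next came a 21-nt sequence seen only in infected leaf (501 reads, 198-fold, lower bound 160). After it were TTAATGTGATGAAGGCGTTGA (639 against 4, 189-fold) and TTACTAAGTGTAGCAAGCGGG (346 against 0, 136-fold, lower bound 110). The lowest, with 0 again taken as 3, was GCTTTTTATACGCGATGGTCG (0 against 1960, 552-fold, lower bound 449). Then came GCGGCATCTTCAAGATTCCC, counted with the miR172 partner strand (1 against 499, 422-fold), and TTAATGTGATGAAGGCGATGA (2 against 952, 402-fold). The others were AGGCGCCATTAGAACAGGTAC (1 against 437, 369-fold) and TAATGTGATGAAGGCGATGAG (0 against 864, 243-fold, lower bound 198). Some of these also have 1-base variants that run the other way between leaf and the other libraries.

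As a background of the matching rule, 540 shuffled references took 0 reads in each library. Bases in random order rarely lie within 2 mismatches of any read, so this count does not show how often related or foreign sequences are taken. Crucifer-specific families, which lettuce is thought to lack, had 2, 0 and 21 reads in leaf, flower and infected leaf, and animal families had 58, 47 and 141.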

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

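The test of scaling, which replaced one whose outcome the choice of families fixed, both tests of the 1-base pairs and the 10-read setting for pairs were chosen after the result, or part of it, was seen.

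Signals appeared in data outside the main comparisons, above the 3 reads taken for a count of 0. Reads of crucifer miR158 numbered 21 in infected leaf by the family matching rule, which allows mismatches. By exact matching, 6 other crucifer small RNAs had 0 reads in each library, a stricter rule than that used for miR158. By the family matching rule, animal let-7a had 20, 15 and 14 reads in leaf, flower and infected leaf, against 5, 1 and 4 exact reads. Animal miR-1 had 38, 32 and 125 reads by the family matching rule. Fungal 5.8S reads numbered 3, 3 and 11, with overlapping intervals, and oomycete 5.8S reads 0, 0 and 42. Among reads of 28 and 29 nt, 60.3% in leaf, 58.8% in flower and 59.2% in infected leaf ended in the first 7 bases of the 3' adapter.

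Animal miR-1 was highest in infected leaf, where its arthropod form had 106 exact reads against 6 in leaf and 15 in flower. Its vertebrate form had 26, 15 and 14 exact reads in leaf, flower and infected leaf, and in infected leaf 0.637 times the RPM of leaf (0.307 to 1.27). A vertebrate source of the excess in infected leaf is argued against by this form, which was not higher there. The 7 other vertebrate microRNAs gave 2 exact reads in infected leaf. They cannot decide the question, since they gave 0 in leaf and flower, where the vertebrate form of miR-1 was also read. Arthropod RNA in the infected leaf material remains a candidate source: 10 other arthropod microRNAs gave 28 exact reads there, against 1 in leaf and 4 in flower, from 5 of the 10. Carry-over from an arthropod library on the same instrument, and the origin of the vertebrate-form reads, were not tested.

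Higher miR156 with lower miR172 in infected leaf held under every scaling run. The lowest fold was 2.02 for miR156 (1.98 to 2.05) and 3.20 for miR172 (3.10 to 3.30). A scaling moves both families the same way, here by -0.41 to 0.72 on the log2 scale, against log2 ratios of 1.42 and -2.39. These values were known when the test was written, so its outcome was fixed and it gives no verdict on scaling. Scaling to added RNA of known amount was not tested. The ratio of miR156 to miR172 was 14.1 times that of leaf (10.8 with no mismatch), and in flower 1.01 times (0.568 with no mismatch). RNA breakdown stays open, because shortened forms of 18 and 19 nt among miR172 reads were 1.33 times as frequent as in leaf, with an interval of 0.383 to 4.64. Leaf age, the plants' developmental phase and the infection itself were not tested, and the labels give no plant age.

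Pairs of 21- or 22-nt small RNAs that differ by 1 base and switch between libraries numbered 7, in 4 independent pairs after those sharing 10 bases were joined, and leaf was the odd library in each. Gene copies used differently in leaf and flower would make flower the odd library. It was odd in 0 of the 4 independent pairs at 20 reads of a pair per library (upper bound 60.2%), which left this test undecided. At 10 reads, a setting chosen after part of the result was seen, flower was odd in 0 of 7 independent pairs (upper bound 41.0%). That bound was 45.9% without the pair seen before the tests. Both lie under the limit of the test, so its answer depends on this setting. A test added later asked whether infected leaf, which is leaf tissue, carried the form of flower. It did in all 7 pairs found at 20 reads, before pairs were joined (lowest lower bound of its share of reads with that form 89.4%). The rule that made leaf odd already fixed this outcome, so the later test decides nothing. A plant genotype of the leaf library that differs from the other libraries remains a candidate explanation, since the lower exact bound of the share of pairs with leaf odd was 39.8%, above the share that chance gives for 1 of 3 libraries. One pair had been seen before the tests were written, and without it leaf was odd in 3 of 3 at 20 reads of a pair per library (lower bound 29.2%, below that share) and in 6 of 6 at 10 reads (54.1%). A change of copy use with infection, growth conditions or age was not tested, and the series' text names 1 cultivar for all plants.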

How the results depend on the processing

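The adapter, 20 to 24 nt and 10-read settings, and every rescaling of the sequence counts, were chosen after seeing the data; the other settings were set before the data were examined. No paired analysis was possible because each group has 1 library. Settings that need a genome were not run. Across settings, no called family reversed. Causes were not tested unless a setting leaves out reads or families by construction. Precision of families with few reads is limited by depth.

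Values are in the order leaf, flower, infected leaf. The 24-nt share moved to 8.08, 24.6 and 7.56% in reads of 18 to 26 nt, 17.5, 35.4 and 15.3% of distinct sequences, 1.19, 8.71 and 1.64% without sequences read once, and 8.28, 25.01 and 7.75% without the 10 most abundant. Flower was highest in each. The 21-nt share moved to 56.4, 39.7 and 54.7%, 26.3, 17.2 and 28.2%, 67.0, 60.2 and 64.9%, and 51.2, 32.9 and 48.0% in the same order of settings, and to 52.4, 37.6 and 51.3% with adapter remainders removed, which left the 24-nt shares within their intervals. The conserved miRNA share moved to 4.22, 2.78 and 5.28% with no mismatch, 5.91, 5.02 and 7.89% with up to 1, 7.09, 7.29 and 9.21% with a shifted 5' end, and 7.38, 7.53 and 9.66% in reads of 18 to 26 nt.

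Families higher in flower numbered 3 with no mismatch, 9 by the median of ratios and 9 by TMM, in place of 5. Families higher in infected leaf numbered 6 by the median of ratios and 4 with no minimum of reads, in place of 2. Sequences higher in flower numbered 184 by the median of ratios and 194 by TMM, in place of 115, and in infected leaf 349 were higher and 114 lower by the median of ratios, in place of 183 and 219. Counts of lower families stayed within 1.5 times the main count in every setting run. A list median was taken as moved from 0.25 on the log2 scale. In flower over leaf by the median of ratios, the medians were 0.72 (development), 1.22 (nutrient), 1.34 (copper), -0.72 (silencing) and -2.10 (defence), and with no mismatch -0.12 (development), 0.22 (nutrient) and 0.49 (copper). In infected leaf over leaf they were -0.20, -2.0, 1.41, 0.47 and 1.54 by the median of ratios, and -2.04 (nutrient) and -0.81 (copper) with no mismatch. Of the family log2 ratios, 107 moved beyond their interval and 333 did not, and of the named sequences 7 did and 93 did not. Settings that change only the minimum of reads cannot move a family's ratio, so they fall among the 333 by construction.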

Other observations

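The miR172 duplex was read from both strands to different degrees. Its partner strand, which is usually degraded, held 52.9% of the reads of both strands in leaf (95% interval 52.5 to 53.3), 17.8% in flower (17.3 to 18.3) and 10.3% in infected leaf (9.51 to 11.2). In RPM the partner strand fell from 18165 in leaf to 1857 and 354, and the partner GCGGCATCTTCAAGATTCACA had 7240, 1538 and 144 reads. Partner reads take in sequences within 2 mismatches of a partner, which were not themselves required to pair. Of the 32304 miR172 partner reads in leaf, the pairing sequences kept held 7240, 3772 and 595. The miR396 partner strand held 39.98% in leaf, 13.4% in flower and 10.97% in infected leaf. The shares of miR167 were 2.41%, 0.895% and 0.685%, and those of miR168 3.99%, 1.89% and 2.77%, so leaf had the highest share in each of the 4 families with a partner found. Partners needed at least 100 reads, so a form high in a single library entered more easily, which may raise the leaf shares. A miR167 partner ran the other way, at 53 leaf, 78 flower and 98 infected leaf reads. The other partners kept had most reads in leaf.

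Forms of a family took different shares of its reads between libraries. Of the reads of a pair of miR167 forms, TGAAGCTGCCAGCATGATCTA made up 32.9% in leaf (32.1 to 33.6), 94.8% in flower (94.4 to 95.1) and 18.2% in infected leaf (17.7 to 18.7), while the family total in flower was 0.906 times that of leaf. Of 3 miR164 forms, TGGAGAAGCAGGGCACGTGTA made up 12.1% in leaf, 3.53% in flower and 55.7% in infected leaf. Of 3 miR156 forms, TGACAGAAGAGAGTGAGCATA made up 17.7%, 26.1% and 38.8%. These forms were chosen after the reads were seen.

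Among 1-base variants of the 54 most read sequences of 20 to 22 nt, A-to-C changes held 52.5% of variant reads in leaf, 54.0% in flower and 50.7% in infected leaf. The variant A20C of the leading miR172 sequence had 9.64%, 10.1% and 8.34% of the reads of its parent.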
